A study of Mus musculus with 12 samples.

How the data were processed

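RNA of whole mouse embryos at embryonic day 10.5 was measured on Affymetrix 3' expression arrays, 1 array per sample, after labelling from 250 ng of total RNA, per the labels' protocols. The 12 arrays fall into 4 genotypes of 3 embryos: wild type (wt), homozygous for the acd allele of Acd (acd), lacking p53 (p53), and homozygous for acd while lacking p53 (double). Genotype and replicate number were taken from the sample titles. The labels call the replicates biological. They describe neither allele, and litter and strain are not given in the sources used here.

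The deposited values are log2 expression values. The authors normalized the scanner files with justRMA, which corrects background, normalizes quantiles and summarises probes into probe sets, and they selected genes with BRB-ArrayTools 4.4.0, per the series' design text. Scanner files, scan dates and the authors' own gene lists were not used here. Array medians lay between 5.32 and 5.40 and the values ran from 2.60 to 14.7, so they were used as deposited. RMA forces the arrays to near-equal distributions, so a change in total RNA per embryo cannot be seen in them. No signal over background was given per gene. The values of Bard1 in all genotypes, and at least 1 genotype mean of Apob, Atrip, C1qa, C1qc, Cdx2, Fgf17, Mrc1, Rsad1, Tekt1 and Tubd1, lay around or below the array medians, as did those of Elmo3 and Usp18, and background can compress differences there. For Bard1, Elmo3, Fgf17, Mrc1 and Usp18 no size of a difference is therefore given. For arrays, the number of embryos limits the precision.

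The table held 45101 probe sets, of which 64 were controls. The platform annotation gave 1 gene symbol for 34945 probe sets and several for 932, and it did not list 9211, of which 9160 were not controls. Symbols were matched through gene identifiers to a RefSeq table of assembly GRCm38.p6, which matched 34754 probe sets and changed 0 symbols. That assembly was used for names, chromosomes and neighbours of genes alone. Each gene was represented by its probe set with the highest mean over the 12 arrays. A gene was tested if that probe set lay above the 40th percentile of its array in at least 3 arrays, which left 13501 of 18194 genes. The p53 transcript was not analysed here.

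Genes were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0). A mean per genotype was fitted to all 12 arrays (8 residual degrees of freedom), with empirical Bayes moderation, two-sided tests and Benjamini-Hochberg adjustment over the genes of each comparison, at an adjusted p of 0.05. The comparisons were acd against wt, p53 against wt, double against p53, double against acd, double against wt, and the interaction, which is the double minus p53 difference less the acd minus wt difference. Gene lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Of 25 lists, 23 had at least 5 tested members. The list of placental genes (Rhox5 and Hand1 measured) and that of sex-linked genes (4 measured) were too short, with medians of 0.21 and 2.94 in acd against wt. The lists of apoptosis machinery, hypoxia and glycolysis, endothelium, neural progenitors, neural crest and urogenital ridge passed camera in none of the 6 comparisons.

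Genes named in the text follow a rule: Acd; in each comparison up to 8 genes with the largest rise and 8 with the largest fall among those that passed, or the 3 with the smallest p where none passed; and up to 4 members of each list with the smallest p. Other names are said to have been chosen after their values were seen. The comparisons, lists, naming rule and most of the alternative settings were fixed before the data were examined. List tests were fixed for every comparison but double against wt, where they were added to the plan. The alternatives were a replicate block, other filters and probe set rules, other normalizations, other variance models and array weights, other thresholds, only the arrays of the genotypes compared, and leaving out each array in turn.

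Other steps were chosen after the values were seen. These were 4 further subsets of arrays, sex as a term of the fit, a test of the Hox genes in 6 comparisons, with sex as a term and without double mutant replicates 1 and 2, 414 Fisher tests of chromosomes, and 22 of the 22 tests that weigh explanations or other splits of the arrays. The Hox family was picked from the ranked genes, and the patterns weighed in the closing section were picked from the per-array values, so their p-values describe these arrays and are not tests of a prior hypothesis. The test for DNA linked to the p53 allele was replaced after its result was seen: the share of genes on chromosome 11 cannot set that explanation apart from others, so it was weighed on the double and acd arrays. Those cannot decide it either, as the labels do not say whether acd embryos carried such DNA.

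The gene test was checked on simulated data built on these 13501 genes, with 50 genes changed at each size. In the simulated acd against wt comparison it recovered 56% of genes changed by 0.5 on the log2 scale, 90% of those changed by 1 and 100% of those changed by 2, and called 10 unchanged genes. In the simulated interaction it recovered 28%, 76% and 94%. A list shifted by 0.3 was recovered by camera with both correlations in the simulated acd against wt comparison, and 0 unshifted lists passed. The simulated values were independent between genes, with 1 spread per gene for all genotypes. In the real arrays the estimated correlation ran from -0.02 for the tail bud list to 0.85 for the erythroid list, and double mutants varied more than wt. The check therefore does not show that the preset correlation or these recovery rates hold for the real arrays.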

Results

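Expression was measured in 12 whole mouse embryos at midgestation, 3 of each of 4 genotypes. Acd encodes TPP1, a protein of the shelterin complex that protects telomeres, and p53 is the transcription factor that halts or kills cells with damaged DNA. The series' design asks which part of the response to homozygous acd depends on p53. Values are RMA log2 values. Correlations between arrays over 13501 genes ran from 0.967 to 0.998. Double mutant replicates 1 and 2 stood apart, with median correlations to the other arrays of 0.972 and 0.987, against at least 0.995 for the other 10 arrays. The median SD between embryos of a genotype was 0.06 in wt, 0.07 in acd, 0.10 in p53 and 0.21 in double mutants. Y-linked transcripts were present in 1 of 3 wt, 3 of 3 acd, 3 of 3 p53 and 1 of 3 double mutant embryos, so sex differs between the genotypes. Sex as a term of the fit is therefore estimated within wt and double mutants alone. The male double mutant is replicate 1, which stood apart, so this term also carries part of its difference into other comparisons. A call that ended with this term cannot be put down to sex.

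The targeted transcript Acd was read by 1 probe set. It measured 8.99 ± 0.01 in wt, 8.91 ± 0.12 in p53, 8.26 ± 0.05 in acd and 8.36 ± 0.11 in double mutants (SD, n = 3 each). Every acd and double mutant array lay below every wt and p53 array. The labels do not describe the allele, so where the probe set lies relative to the altered part is not known, and the p53 transcript was not analysed here.

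**Figure D1:**
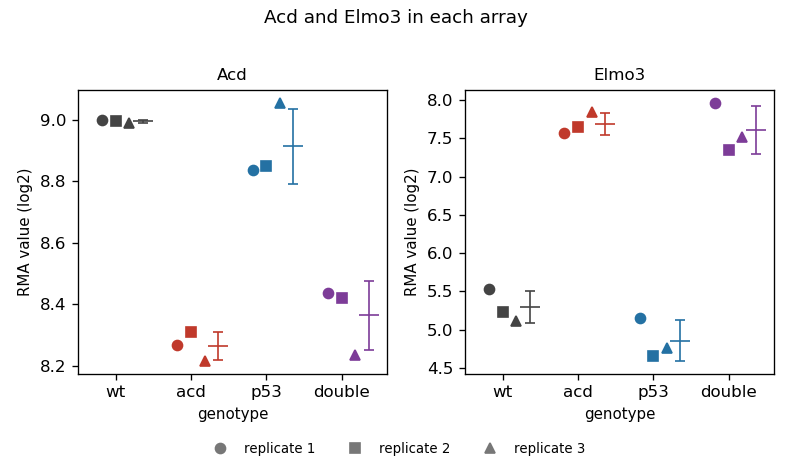
RMA values (log2) of Acd and Elmo3 in each of the 12 arrays by genotype, with the mean and SD of the 3 embryos beside the points. Acd averages 8.26 in acd against 8.99 in wt embryos, and Elmo3 averages 7.69 in acd and 7.61 in double mutant embryos.

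In embryos with p53, acd against wt asks what homozygous acd alone changes. Elmo3, an engulfment and cell motility protein whose gene lies near Acd on chromosome 8, was higher (adjusted p = 0.000216), at 7.57 to 7.85 in the 3 acd arrays, and Acd fell to 0.603 of wt (log2 -0.73 ± 0.08 SE, adjusted p = 0.0113). Elmo3 measured 4.66 to 5.53 in the wt and p53 arrays, around or below the array medians and not shown to be above background, so no difference is given for it. No other gene passed limma's test, 239 having an unadjusted p under 0.05, where chance alone would give 675 in each comparison. The spread per gene is shared by all genotypes, with a median SD of 0.21 in double mutants and 0.06 in wt. The test may therefore be too strict here, so few calls do not show a lack of effect. As a list, p53 target genes rose (camera adjusted p = 0.00021, or 0.507 with an estimated correlation), with 21 of 28 members higher and a median of 0.09. Cdkn1a, the cell cycle inhibitor p21, measured 0.54 ± 0.19, Ddit4l 0.31 and Sesn2 0.29, and 0 members passed over all genes or adjusted over the list alone. The list median and these 3 genes measured 0.03, 0.36, 0.17 and 0.13 without acd replicate 3, and 0.15, 0.84, 0.55 and 0.51 without acd replicate 1. Transcripts of visceral endoderm and liver rose (adjusted p = 0.00021, or 0.707 with an estimated correlation), with 12 of 12 members higher and Afp at 0.36. With sex as a term, chosen after seeing the data, their median was -0.0035 and the call ended (adjusted p = 0.642). In this list the male double mutant, replicate 1, lay at 1.39 relative to wt and replicates 2 and 3 at 1.14 and 0.25. This difference enters the sex term, so the loss cannot be put down to sex. Transcripts of the integrated stress response rose slightly (adjusted p = 0.00729, or 0.507 with an estimated correlation), with Hsp90b1 at 0.16 and Mthfd2 at 0.21. The DNA replication list rose (adjusted p = 0.0321, or 0.714 with an estimated correlation), with Ccne1, cyclin E1, at 0.18.

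Transcripts of differentiating neurons fell (camera adjusted p = 7.17e-05, or 0.707 with an estimated correlation), with 17 of 18 members lower. Pou4f1, a sensory neuron transcription factor, measured -0.34 ± 0.17, Ina, a neurofilament protein, -0.35 and Isl1 -0.15. Without acd replicate 3 Ina measured -0.18 and Isl1 -0.09, and the list median was -0.07 in place of -0.20, while without acd replicate 1 it was -0.33. Somite and muscle precursor transcripts fell (adjusted p = 0.00729, or 0.507 with an estimated correlation), with 13 of 16 lower, among them Uncx at -0.36 and Tcf15 at -0.15. In each of these 6 lists 0 members passed adjusted over the list alone. Among telomere genes Acd alone passed adjusted over the list alone, and Terf1 measured 0.20, or 0.11 without wt replicate 1. The Acd call ended when any 1 of the 6 wt and acd arrays was left out (adjusted p 0.054 to 0.131), while its change stayed between -0.75 and -0.71. Over 14 other settings its adjusted p ran from 3.57e-05 to 0.0883. Without acd replicate 3 the p53 target and neuron lists did not pass (adjusted p 0.148 and 0.155). With sex as a term the calls of Acd (adjusted p = 0.0645) and of p53 targets (0.0507) ended too.

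p53 target transcripts differed between the acd embryos. Ccng1, cyclin G1, measured 8.34 in acd replicate 1 against 10.16 and 10.34 in replicates 2 and 3, and 8.75 to 9.26 in wt. Cdkn1a measured 8.02 against 8.83 and 8.99, and Phlda3, an inhibitor of Akt signalling, 7.21 against 8.06 and 8.16. The Acd value of the same array, 8.27, lay with the other acd arrays. Ccng1 and Phlda3 are named here after their values were seen. Without acd replicate 1, Cdkn1a passed in acd against wt (0.84, adjusted p = 0.00549, against 0.00322 to 1 over 14 other settings), 3 genes passed, and 11 lists passed.

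**Figure D2:**
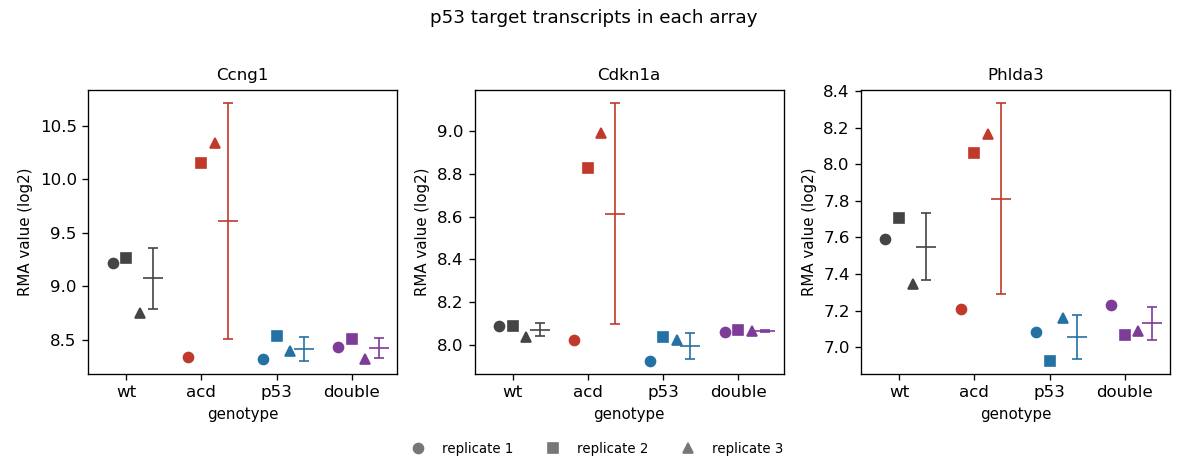
RMA values (log2) of Ccng1, Cdkn1a and Phlda3 in each of the 12 arrays by genotype, with the mean and SD of the 3 embryos beside the points. In acd replicate 1 Ccng1 is at 8.34, while replicates 2 and 3 are at 10.16 and 10.34.

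p53 against wt asks what loss of p53 alone changes. No gene passed limma's test, and 98 had an unadjusted p under 0.05, against 675 expected by chance. As in acd against wt, so few small p-values do not show a lack of effect. The smallest p-values, none passing (adjusted p = 1), were those of Glod4 (-0.82 ± 0.15), Cuedc1 (0.45 ± 0.09) and Scpep1 (0.49 ± 0.11). Cuedc1 has 3 probe sets, which measured 0.16, 0.45 and 2.15. Another probe set of Scpep1 measured -0.0007, so its rise rests on the probe set used. p53 target genes fell as a list (camera adjusted p = 0.0237), with 23 of 28 lower, Phlda3 at -0.49 ± 0.20 and Ccng1 at -0.66 ± 0.39. Primitive erythroid transcripts fell (adjusted p = 0.00936), with 16 of 16 lower and Klf1, an erythroid transcription factor, at -0.45, or -0.26 without wt replicate 3. Endoderm and liver transcripts rose (adjusted p = 0.00338) and limb bud transcripts rose (adjusted p = 0.0393; Fgf10 0.34). In these lists 0 members passed adjusted over the list alone, and each list had an adjusted p of 0.978 with an estimated correlation. The endoderm and liver median turned to -0.11 without p53 replicate 2, whose list mean lay 1.10 above wt, and the call ended with sex as a term, chosen after seeing the data (adjusted p = 0.759). The p53 target call ended without any of wt replicates 1 and 2 or p53 replicates 1 to 3 (adjusted p 0.0522 to 0.223) and with sex as a term (0.21), and the erythroid call without wt replicate 3 or p53 replicate 3 (adjusted p 0.882 and 0.836). Without p53 replicate 3, 1 gene passed.

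Double against p53 asks what homozygous acd changes without p53. Elmo3 was higher (adjusted p = 4.61e-05), at 7.35 to 7.96 in the double mutant arrays against 4.66 to 5.16 in the p53 arrays, which are not shown to be above background, and was the only gene to pass, with 1451 at an unadjusted p under 0.05. Acd measured -0.55 ± 0.08 (adjusted p = 0.183). Interferon response transcripts rose as a list (camera adjusted p = 8.76e-11), with 13 of 13 members higher, 10 passing adjusted over the list alone and 0 over all genes. Rsad2, the antiviral protein viperin, measured 2.90 ± 0.73 and Irf9 1.97 ± 0.50. Usp18, an interferon-induced protease, was at 10.68 and 10.01 in double mutant replicates 1 and 2 and at 3.72 to 4.97 in the other 10 arrays, not shown to be above background, so no difference is given for it. Macrophage transcripts rose (adjusted p = 1.49e-06), with 16 of 17 higher and Mrc1 passing adjusted over the list alone. Endoderm and liver transcripts rose (adjusted p = 0.000484), and Alb (1.98 ± 0.51), Serpina1b (0.88, or 0.53 without double mutant replicate 1) and Fgb, a fibrinogen chain (0.58), passed adjusted over the list alone. With an estimated correlation the adjusted p was 0.521, 0.521 and 0.549. The interferon and macrophage lists were high in the arrays that stood apart: the interferon list mean lay 2.62 and 2.28 above wt in double mutant replicates 1 and 2 and 0.16 in replicate 3, and the macrophage list mean 1.24, 0.83 and -0.24. The endoderm and liver list mean lay 1.39, 1.14 and 0.25 above wt in these arrays and 1.10 in p53 replicate 2, which did not stand apart.

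Transcripts of DNA damage response and repair fell in double against p53 (camera adjusted p = 8.72e-06), with 26 of 29 lower, Hus1 at -0.45 and Atrip at -0.37. Hus1 measured -0.26 without double mutant replicate 1, and without replicates 1 and 2 Hus1 measured -0.03 and Atrip -0.06. Those of tail bud and posterior axis fell (adjusted p = 0.000484), with 13 of 16 lower and Cdx2, a posterior patterning factor, at -0.49, or -0.32 without p53 replicate 3. Heart muscle transcripts fell (adjusted p = 0.026), with Myh6 at -0.74, or -0.35 without double mutant replicate 1. In these lists 0 members passed adjusted over the list alone. With an estimated correlation the adjusted p was 0.549 for repair, 0.0728 for tail bud and 0.586 for heart, and fry passed the tail bud list alone (adjusted p = 0.00774). The other lists that passed were DNA replication, G2 and mitosis and telomere genes, which fell, and erythroid, neuron, immediate early and secreted inflammatory genes, which rose; Igfbp3 (0.43, or 0.28 without double mutant replicate 1) and Timp1 (0.32) passed adjusted over the last list alone. None of these 7 lists passed with an estimated correlation (adjusted p 0.521 to 0.586). Relative to wt, the means of the 3 falling lists lay at -0.30 to -0.08 in double mutant replicates 1 and 2 and at -0.01 to 0.04 in replicate 3, and those of the 4 rising lists at 0.10 to 0.67 in replicates 1 and 2 and at -0.45 to -0.01 in replicate 3. p53 target genes did not pass (adjusted p = 0.742), and Bbc3, the apoptosis activator Puma, measured -0.31 and passed adjusted over the list alone. Without double mutant replicate 3, 1756 genes passed. Leaving out replicates 1 and 2, an alternative chosen after seeing the data, leaves 1 double mutant embryo. The macrophage median was then -0.20 and the repair median 0.03, values that describe replicate 3 alone. Without p53 replicate 3, 2 genes passed, and without double mutant replicate 2, 3 genes and 7 lists. The heart call ended without double mutant replicate 3 (median 0.05) or p53 replicate 2 (adjusted p = 0.091), with the 60th percentile filter (0.107) and with sex as a term, chosen after seeing the data (median 0.09, adjusted p = 0.923). The repair call ended without double mutant replicate 1 (adjusted p = 0.123).

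**Figure D3:**
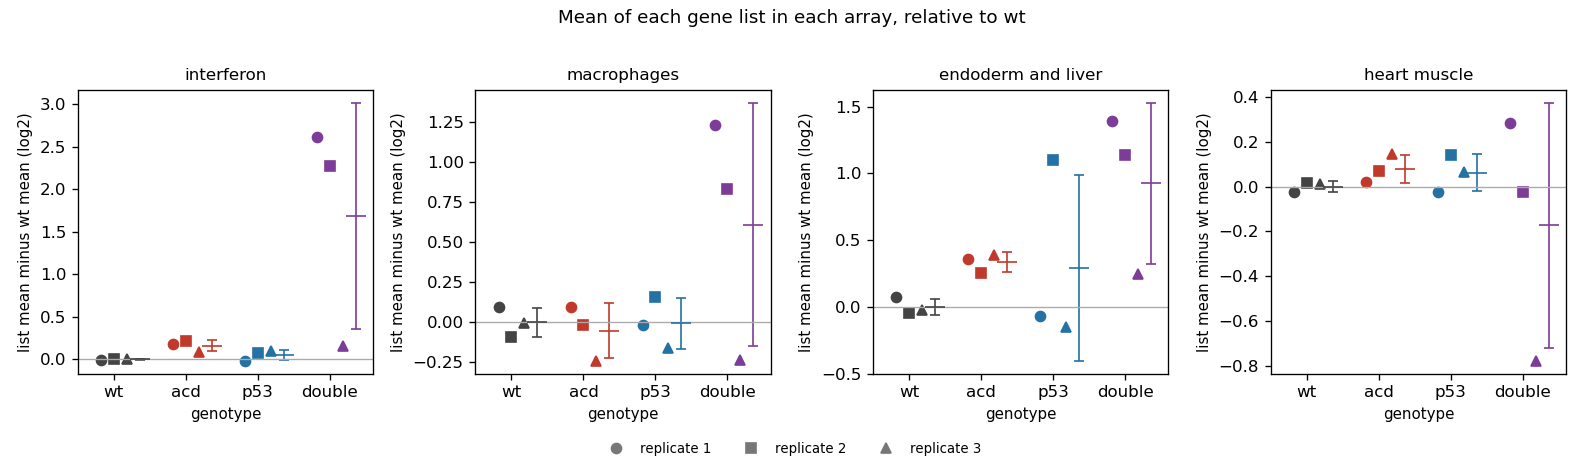
Mean of 4 gene lists in each of the 12 arrays, as the log2 difference from the wt mean, with the mean and SD of the 3 embryos beside the points. The interferon list is at 2.62 and 2.28 in double mutant replicates 1 and 2 and at 0.16 in replicate 3, whose heart muscle list is at -0.78.

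Double against acd asks what loss of p53 changes in homozygous acd embryos. No gene passed limma's test, with 1700 at an unadjusted p under 0.05. The smallest p-values were those of Irs4, an insulin receptor substrate (-1.09 ± 0.16, adjusted p = 0.258), Mybpc3, a heart muscle protein (-0.56 ± 0.09, adjusted p = 0.371), and Bard1, the partner of Brca1 (lower, adjusted p = 0.371), whose values are not shown to be above background. p53 target genes fell as a list (camera adjusted p = 0.00012), with 21 of 28 lower and Phlda3 at -0.68 ± 0.20, Aen at -0.41 and Gtse1 at -0.39, or -0.23 without double mutant replicate 1, 0 passing adjusted over the list alone. Neuron transcripts rose (adjusted p = 8.79e-07), with 18 of 18 higher, Stmn2 at 0.92 and Tubb3 at 0.48, and interferon transcripts rose (adjusted p = 4.5e-09), with 10 of 13 passing adjusted over the list alone. With an estimated correlation these 3 lists had an adjusted p of 0.361. Of 12 lists that passed, the tail bud list also passed fry (adjusted p = 0.0434) but did not pass with an estimated correlation (adjusted p = 0.355). Its members Cyp26a1 (-0.51) and Fgf17 (lower) passed adjusted over the list alone. Without double mutant replicate 3, 1876 genes passed and the p53 target list did not (adjusted p = 0.0507); without acd replicate 1, 4 genes passed and Phlda3 was among them (-0.98, adjusted p = 0.03). Leaving out double mutant replicates 1 and 2, chosen after seeing the data, leaves 1 double mutant embryo. Its interferon list mean lay 0.16 above wt, within the 0.09 to 0.21 of the acd arrays.

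Double against wt gives the combined difference and shares its wt arrays with both single mutant comparisons. Its list tests were not fixed beforehand. Elmo3 was higher (adjusted p = 0.00031), against wt values not shown to be above background, and Acd fell to 0.646 of wt (log2 -0.63 ± 0.08, adjusted p = 0.0492). Of the 23 lists 10 passed camera, led by interferon genes (adjusted p = 5.85e-11), endoderm and liver genes (adjusted p = 4.93e-07; Alb 2.01, Fgb 0.83) and macrophage genes (adjusted p = 5.4e-07). The adjusted p with an estimated correlation was 0.478, 0.478 and 0.494. Relative to wt, double mutant replicates 1 and 2 lay at 2.62 and 2.28 for interferon, 1.39 and 1.14 for liver and 1.24 and 0.83 for macrophages, and replicate 3 at 0.16, 0.25 and -0.24. Without double mutant replicate 3, 1646 genes passed. The Acd call ended without any 1 of 9 arrays, which are all but p53 replicate 3 and double mutant replicates 1 and 3 (adjusted p 0.0757 to 0.436). It also ended in 7 of 13 other settings, a replicate block among them.

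Of the 2 genes called in acd against wt, both had the same sign in double against p53, and Elmo3 was called in both. The level that Elmo3 reached was similar in acd and double mutant embryos, with and without p53. Both Elmo3 calls start from values not shown to be above background. Whether the size of its difference depends on p53 can therefore not be read from them. As Elmo3 lies near Acd, an effect of acd on it cannot be told apart from a difference in DNA linked to the acd allele. The labels do not describe that allele, and strain is not given. Over all 13501 genes the changes of these comparisons, which share no array, correlated at r = -0.05 (Spearman 0.08); genes are not independent replicates. The interaction itself, the test of whether the acd effect differs without p53, passed for no gene in limma, with 531 at an unadjusted p under 0.05. Mybpc3 (-0.65 ± 0.13), Bard1 (lower) and Irs4 (-1.06 ± 0.22) had the smallest p-values and did not pass (adjusted p = 0.879). Without double mutant replicate 3 the interaction passed for 439 genes. Of the lists, 9 passed camera. Interferon (median 1.58), macrophage (0.76) and neuron genes (0.42) were higher, and p53 target genes (-0.15; Bbc3 -0.35), repair, replication, mitosis, tail bud and heart genes were lower. With an estimated correlation none passed, the lowest adjusted p being 0.166. The p53 target call ended without wt replicate 3 (adjusted p = 0.0793), acd replicates 2 (0.128) or 3 (0.166), or double mutant replicate 3 (0.284), where its median ran from -0.13 to -0.07, and also with array weights (0.212) and with sex as a term (0.391). Sex as a term, chosen after seeing the data, also ended the neuron call (adjusted p = 0.0887), and 5 lists passed with it. The heart call ended without double mutant replicate 3 (median -0.04, adjusted p = 0.923), whose heart list mean lay at -0.78 relative to wt against 0.28 and -0.03 in replicates 1 and 2, and with sex as a term (median 0.26, adjusted p = 0.983). The tail bud call ended without double mutant replicate 3 (adjusted p = 0.0874) and with sex as a term (0.175), and its median was -0.27 without p53 replicate 1. The repair and mitosis calls ended without double mutant replicate 1 (medians -0.04 and -0.02, adjusted p 0.24 and 0.396) and the mitosis call without p53 replicate 1 (0.0706), and their medians were -0.41 and -0.24 without double mutant replicate 3. Leaving out double mutant replicate 1 also moved the medians of macrophage, replication, heart and p53 target genes to 0.39, -0.10, -0.60 and -0.09, and leaving out replicate 2 that of neuron genes to 0.27. A fit without double mutant replicates 1 and 2, chosen after seeing the data, leaves 1 double mutant embryo. In it the medians of interferon, macrophage, repair, replication and mitosis genes were -0.0194, -0.13, 0.03, 0.01 and 0.04. Males made up 3 of 3 acd and 3 of 3 p53 embryos but 1 of 3 wt and 1 of 3 double mutants, so sex lines up in part with the interaction.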

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

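The tests of explanations and of other splits of the arrays were chosen after the results were seen, while the interaction test was not. The 9 lists below differed in their acd effect between embryos with and without p53 by the interaction test with camera's preset correlation, and none did with an estimated correlation. Sex lines up in part with this interaction, as Y transcripts were in 3 of 3 acd and 3 of 3 p53 but 1 of 3 wt and 1 of 3 double mutant embryos. Of 6 genes with an interaction p under 0.001, 4 lay on the X chromosome (Fisher's exact test, adjusted p = 0.00148 over 414 tests). Under 0.01 it was 6 of 49 (adjusted p = 0.151) and under 0.05 it was 22 of 531, neither passing. Of 5 tested Y-linked genes, 3 were among the 49 (adjusted p = 0.000185) and 3 among the 531 (adjusted p = 0.0295), both passing Fisher's exact test, and 0 among the 6. Y transcripts follow the sex of the embryos, so sex does enter the interaction of single genes. Whether sex underlies the list calls is not shown by these counts. With sex as a term 5 lists passed, and the p53 target, neuron, heart and tail bud calls ended (adjusted p 0.391, 0.0887, 0.983 and 0.175). All acd and p53 embryos are male, so this term also holds the difference of double mutant replicate 1 from replicates 2 and 3. Without double mutant replicate 3, whose heart list mean lay at -0.78 relative to wt against 0.28 and -0.03 in replicates 1 and 2, the heart, tail bud and p53 target calls ended (adjusted p 0.923, 0.0874 and 0.284). The repair and mitosis calls ended without double mutant replicate 1 (0.24 and 0.396), the mitosis call without p53 replicate 1 (0.0706), and the p53 target call without wt replicate 3 (0.0793), acd replicate 2 (0.128) or acd replicate 3 (0.166). Without double mutant replicates 1 and 2, which leaves 1 double mutant embryo, the medians of interferon, macrophage, repair, replication and mitosis genes were -0.0194, -0.13, 0.03, 0.01 and 0.04. The median interaction on the log2 scale was 1.58 for interferon genes, 0.76 for macrophage genes, 0.42 for differentiating neurons, -0.24 for DNA damage response and repair, -0.17 for DNA replication, -0.30 for heart muscle, -0.16 for tail bud and posterior axis, -0.15 for G2 and mitosis and -0.15 for p53 target genes. Of 100 drawn assignments of the 12 arrays to genotypes, the real one included, 41 passed at least 9 lists and the highest of the others passed 15, so chance is not excluded for this count.

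In double mutant replicates 1 and 2, interferon transcripts were high: Usp18 measured 10.68 and 10.01 against at most 4.97 in the other 10 arrays. Degraded RNA is argued against, since the actin 3' minus 5' difference was 0.48 and 0.39 in these arrays and 0.37 to 0.51 in the others; the bioB control spike was higher, at 9.03 and 8.82 against 8.39 to 8.69, and that stays unexplained. More macrophages with resting interferon levels are argued against, since the interferon list mean exceeded the macrophage list mean by 1.38 and 1.45, with an SD of 0.17 in the other arrays. Of the macrophage list 17 genes were measured in these embryos, and its most abundant in wt, Csf1r, was at 8.85 and 8.49 against a wt mean of 7.78, while Ctss was at 9.62 and 8.61 against 6.63; activated macrophages stay open. Maternal tissue is argued against for replicate 1, whose Xist (4.75) lay within the 4.64 to 5.51 of the 7 other arrays with Y transcripts, and cannot be told apart for replicate 2, a female embryo with its own Xist (11.91). As replicate 3 has the same genotype label and lacks the rise, an effect of the double mutant genotype with variable onset may exist but was not tested. Other differences between these embryos, in which Lin28a, Prtg and Trim71 were also lower, were not weighed, so a genotype effect is not the only account left.

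In acd replicate 1, p53 target transcripts lay near the p53-null arrays. Over Ccng1, Phlda3 and Trp53inp1, the 3 fixed targets whose p53 values all lay below all wt values, its median was -0.34 relative to the wt mean, against -0.54 to -0.39 in p53 and -0.20 to 0.16 in wt. This is consistent with a p53-null embryo or a wrong p53 label, as a hypothesis. A swap with a double mutant array is argued against only for a swapped acd embryo with raised p53 targets. The highest p53 target list mean among the double mutant arrays was -0.0313, below 0.20 and 0.26 in the other acd arrays. That value lay within the -0.06 to 0.0402 of the wt arrays. A swap with an acd embryo whose p53 targets were not raised can therefore not be told apart. For acd replicate 1 itself, p53 intact but not activated cannot be told apart either. Its median minus that of the lowest wt array was -0.14, a smaller distance than the 0.19 SD of the wt arrays.

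For the pairwise comparisons the 10 splits of 6 arrays are too few for a share under 0.05. Genes called numbered 2 in acd against wt (highest other split 0), 0 in p53 against wt (0), 1 in double against p53 (13), 0 in double against acd (0) and 2 in double against wt (0); 1, 10, 2, 10 and 1 of the splits reached the real count. Lists passing numbered 6 (highest other 9), 4 (5), 13 (11) and 12 (11) in the first 4 comparisons, and 4, 4, 1 and 1 splits reached that. The split that called 13 genes set p53 replicate 2 and double mutant replicates 1 and 2 against the other 3 arrays, a structure of the samples that genotype does not follow; its cause was not tested. For the interaction, 100 of 100 assignments reached its count of 0 genes (highest other 1). A count of 0 is reached by every split, so it says nothing about chance here, in p53 against wt or in double against acd. For genes called in both acd comparisons, 1 of 100 combined splits, the real one, reached the real count of 1 (highest other 0). That is the lowest share these splits can give. The count rests on Elmo3 alone and the test was chosen after it was seen, so this argues against chance for that count without excluding it.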

How the results depend on the processing

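Alternatives named as added were chosen after seeing the data, as were sex as a term and the subsets of arrays. The replicate numbers were not taken to pair the arrays, as the labels do not say what they mark and 7 of 18 same-number pairs correlated over 0.1 (-0.23 to 0.39), with 5 of 12 arrays correlating best with their own number. All 6 such pairs of replicates 2 and 3 among p53, acd and double mutants were over 0.1, a subset picked after seeing the values, so a shared litter or day is not excluded for them. With a replicate block 1 gene passed in acd against wt and 1 in double against wt, and Acd stayed at -0.73 and -0.63 with an adjusted p of 0.0883 and 0.202; the cause was not tested, and with only the 2 genotypes the first was 0.00322. Acd has 1 probe set, so a value for each probe set could not differ. In double against wt 1 gene passed with no filter, with every probe set, with median centring and with repeated quantile normalization, and 0 with only the 2 genotypes; the cause was not tested. With the 60th percentile filter 10 lists passed in acd against wt. With array weights 122 genes passed in double against p53, 1774 in double against acd and 1805 in double against wt, and 2 in both acd comparisons; replicate 1 and 3 of the double mutants had weights of 0.068 and 0.246. At an unadjusted p of 0.001 the counts were 4, 5, 17, 13, 19 and 6 in the order of the comparisons, the interaction last. With an estimated correlation 0 lists passed in each comparison, and with fry 0, 0, 1, 1 and 0 in acd against wt, p53 against wt, double against p53, double against acd and the interaction. Without double mutant replicates 1 and 2 (added), which leaves 1 double mutant array assumed to vary like the others, 28, 31, 26 and 25 genes passed in double against p53, acd and wt and the interaction, and 2 in both acd comparisons; in double against p53 C1qa turned to -0.24, C1qc to -0.20, Xrcc6 to 0.0147, the macrophage median to -0.20 and the repair median to 0.0344, Acd in double against acd to -0.0288 and the interferon, macrophage, repair, replication and mitosis interactions to -0.0194, -0.1286, 0.0294, 0.0056 and 0.0423. Without acd replicate 1 as well (added), the counts were 24, 33, 22, 20 and 2, 11 lists passed in acd against wt, and the same values for C1qa, C1qc, Xrcc6, macrophages, repair, Acd and interferon were -0.24, -0.20, 0.0147, -0.20, 0.0344, -0.0266 and 0.0181, the last where camera's direction was down, with macrophage, repair and mitosis interactions of -0.0529, 0.0309 and 0.0449. Without acd replicate 1 and double mutant replicate 1 (added), 3 genes passed in double against acd and 1 in double against wt. With sex as a term (added) 1, 1, 2, 1 and 1 genes passed in acd, p53 against wt, double against p53, double against wt and the interaction, Acd measured -0.77 (adjusted p = 0.0645), Zmat3 in p53 against wt 0.0226, the heart interaction 0.2553, and 7 and 5 lists passed in p53 against wt and the interaction. The p53 target median in double against p53, never called, was -0.0045 with the 60th percentile filter, where camera's direction turned, and 0.0051 with array weights. Leaving out each array in turn gave 1 to 3 genes in acd against wt, 0 to 1 in p53 against wt, 1 to 1756 in double against p53, 0 to 1876 in double against acd, 1 to 1646 in double against wt, 0 to 439 in the interaction and 1 to 2 in both acd comparisons, the highest in the last 5 without double mutant replicate 3, and Acd at -0.75 to -0.71. Lists passing ranged from 3 to 11, 1 to 4, 7 to 14, 9 to 12 and 8 to 12. Apob in p53 against wt ran from -0.0934 to 0.90, its liver list from -0.11 to 0.54, and in double against p53 the heart list from -0.43 to 0.0486 and p53 targets from -0.0403 to 0.0302. Of the other values for named genes and lists, 937 under settings fixed beforehand and 1274 with an array left out kept their direction and side of the threshold, 56 and 36 no longer passed, and 24 and 42 newly passed. No signal over background was given per array, and the number of embryos limits each comparison.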

Other observations

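The tests in this part were all chosen after the results were seen. In double mutant replicate 3 the heart muscle list mean lay at -0.78 relative to wt, against -0.03 to 0.28 in the other 11 arrays. The genes named in this paragraph were picked from the most extreme genes of these arrays after their values were seen, and apart from heart muscle no gene group was tested. Myl2, the ventricular myosin light chain, measured 9.24 against at least 11.16 in the other 11 arrays, Nppa, a natriuretic peptide, 7.34 against at least 8.86, and Pln, phospholamban, 4.95 against at least 6.52. Wnt8b measured 5.69 against at least 6.93, Fezf2 5.07 against at least 6.17, Dmrt3 5.37 against at least 6.20 and Six3 6.08 against at least 6.46. In double mutant replicates 1 and 2 Lin28a, a repressor of let-7 maturation, measured 6.18 and 7.27 against at least 8.80 in the other 10 arrays, Prtg 7.89 and 8.66 against at least 9.94, and Trim71 7.74 and 8.64 against at least 9.63.

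Hox genes, which pattern the body axis, were lower in acd than in wt embryos. Of 30 tested, 28 were lower, with a median of -0.18; Hoxa9 measured -0.30 ± 0.08, Hoxd10 -0.34 ± 0.10 and Hoxb9 -0.39 ± 0.14, and 0 passed over all genes or adjusted over the family alone. The list mean relative to wt was -0.13, -0.26 and -0.20 in the acd arrays and -0.04 to 0.02 in the wt arrays. Camera with an estimated correlation gave p = 0.00103, or 0.00618 adjusted over 6 comparisons, and 0.00027 to 0.00459 when each array was left out in turn. With sex as a term p was 0.0419, with 25 of 30 lower and a median of -0.20. The family was picked from the ranked genes, so these p-values overstate the evidence. Without p53 the median acd effect was -0.02 (p = 0.491 with an estimated correlation), and the interaction, with a median of 0.14, did not pass (p = 0.068, adjusted 0.136). The list mean relative to wt was -0.17, -0.07 and 0.02 in the double mutant arrays. With double mutant replicates 1 and 2 left out, the median acd effect without p53 was 0.06 (limma's camera with an estimated correlation, adjusted p = 0.47) and the median interaction 0.23, which passed (adjusted p = 0.0262 over 6 comparisons). The interaction call therefore depends on these arrays. Only replicate 3 then stands for the double mutants.

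Genes on chromosome 11, which carries p53 in mice, led p53 against wt. Of 17 genes with p under 0.01, 8 lay there (Cuedc1, Glod4, Rsad1, Scpep1, Slc16a6, Slfn9, Tekt1 and Tubd1), against 1115 of 13501 tested genes (Fisher's exact test, two-sided, p = 2.61e-05, or 0.00216 adjusted over 414 tests of chromosomes, comparisons and p bars). Regulation of these genes by p53 is argued against: double and acd embryos differ in p53 too, yet the median ratio of their difference to that in p53 against wt was 0.18, with an upper quartile of 0.24. This takes all acd embryos as having p53, although p53 targets of acd replicate 1 lay near the p53-null arrays, and no ratio was computed without it. For DNA of another strain carried along with the p53 allele this ratio cannot decide, as the labels do not say whether acd embryos carried such DNA. Other chromosome 11 DNA in the wt embryos than in the other genotypes may account for the pattern but cannot be told apart: the median ratio of the acd minus wt change was 0.70, and the shared wt arrays favour such a value. At p under 0.01, 39 of 273 genes in double against wt lay on chromosome 11 (Fisher's exact test, adjusted p = 0.0347 over 414 tests). In acd against wt it was 7 of 35 (adjusted p = 0.308), not passing. It was 23 of 229 in double against p53 (unadjusted p = 0.331) and 29 of 306 in double against acd (0.402). All pairwise comparisons with wt share its arrays, so their counts are not independent. Another probe set of Scpep1 measured -0.0007 in p53 against wt. Strains are not given in the sources used here. Elmo3 and Acd lie on chromosome 8 with 15 protein-coding genes between them, and of 74 tested neighbours of Acd only Elmo3 was called in acd against wt.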
